A study of Mus musculus with 23 samples.

How the data were processed

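Total RNA from the colon of BALB/c mice was labelled with biotin and hybridised to 1 Affymetrix array per sample, with 23 arrays in all. The authors deposited log2 expression values for 45101 probe sets on each array. The submitters' processing notes name RMA and GCRMA, 2 methods that correct the background, normalize arrays between each other and summarise the probes of a probe set. Which of them made the deposited values, and its version, is not given in the sources used here. The deposited log2 values ranged from 2.17 to 15.98, and 27.9% stood at the lowest value. Fold changes of genes at that floor are therefore understated, and 1660 genes stood there on all arrays. No 2 arrays held identical values.

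Groups were taken from the sample labels: genotype (wild type or Fn14 knockout) and TNBS (without or with). Probe sets were named from the platform annotation of 2016. Of all probe sets, 34958 named 1 gene, 932 named several and 9211 were unnamed there, and only the first kind was used. Gene IDs of 34754 probe sets matched the genes of assembly GRCm38.p6, which gave current symbols and the genes that lie within set distances of Tnfrsf12a and Ctps2. Its positions served only to find those neighbours and are not printed. Each of 18194 genes was represented by its probe set with the highest mean over all arrays. Probe sets of multigene families (Mcpt, Rnase2a, Oas, Ifit, H2) can hybridise to transcripts of related genes, so their values may belong to several members.

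A linear model with 1 mean per group was fitted to all 23 arrays with limma (lmFit, eBayes, 19 residual degrees of freedom, 0.475 prior degrees of freedom, so spreads were moderated little), and 5 contrasts were tested: TNBS against no TNBS in each genotype, knockout against wild type with and without TNBS, and the difference of the TNBS effects between genotypes. The adjusted p of a gene is from limma after Benjamini-Hochberg adjustment over all genes, with a threshold of 0.05 here and below. Gene lists (41, of which 18 were pathways and 22 cell types) were fixed before the data were examined. Each was tested against all other genes with camera at a preset correlation of 0.01, adjusted over 205 tests, and again with the correlation estimated from the data. The program fry was run as an alternative that tests whether the genes of a list move, on balance, one way, and compares them with no other genes. The adjusted p of a list is from camera at the preset correlation unless an estimated correlation or fry is named, each adjusted over the same 205 tests. The genes named were drawn from Tnfrsf12a and Tnfsf12, per comparison the 10 with the largest positive and the 10 with the largest negative change among called genes whose groups did not overlap (no overlap rule for the difference of TNBS effects), and up to 4 members with the smallest p of each list described. The text prints a selection of these genes, which the rule did not set. Immunoglobulin, T cell receptor and clone names were passed over in the ranking. Single values per array, such as the mean of a list, were compared with two-sided exact permutation tests, adjusted over 8 tests for the means of lists and over 12 for the quality measures.

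The procedure was tested on simulated arrays drawn around each gene's mean over all arrays with its spread within groups, in which genes brighter than the median gene were shifted. Noise was drawn for each gene on its own. Variation that genes share across arrays was therefore not simulated, and false calls that it can give are not measured. For TNBS in wild type, 79.1%, 94.0% and 98.5% of genes shifted by 0.5, 1 and 2 were called, with 11 of 17974 unshifted genes. For knockout against wild type with TNBS the shares were 80.6%, 95.5% and 100%, with 10 unshifted genes called. For the difference of TNBS effects they were 61.2%, 89.6% and 98.5%, with 4. Among 18194 unshifted genes 1 was called for TNBS in the knockout and 1 for the genotypes without TNBS.

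Alternatives fixed before the data were examined were limma's trend and robust options, the 2 compared groups alone, array weights, a filter on dim probe sets, the mean of or every probe set of a gene, quantile normalization, median centring, a minimum fold change, the replicate number as a block, and leaving out each array. Alternatives chosen after seeing the data were a floor at log2 5, leaving out genes at the floor on all arrays, and covariates for the mean of the skeletal muscle list, the mean of the squamous list and the Gapdh 3' minus 5' signal. Analyses used R 4.3.3, limma 3.58.1 and version 1.17.8 of the data.table package, and figures Python 3.11.15 and matplotlib 3.10.9.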

Results

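Gene expression was measured with oligonucleotide arrays in 23 colon samples of BALB/c mice that fall into 4 groups: wild type without TNBS (n = 5), wild type with TNBS (n = 6), Fn14 knockout without TNBS (n = 5) and Fn14 knockout with TNBS (n = 7). Fn14, encoded by Tnfrsf12a, is the receptor for the cytokine TWEAK. TNBS is a hapten that causes colitis when given rectally in ethanol. Per the labels' protocols, a 0.2% solution was injected over 6 weeks, at volumes that rose from 1 to 2 ul per g of body weight, and tissue was taken 3 days after the last injection. The labels do not say whether the untreated groups received ethanol, so a TNBS effect below covers the injections and their solvent as well. They number the samples of a group without stating that each came from its own mouse, so p-values measure the spread between these samples.

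Arrays of 1 group correlated at r = 0.989 to 0.998 with each other over the 18194 genes, each with 1 probe set. The first principal component held 40.4% of the variance, with untreated arrays at -40.5 to -19.5 and TNBS arrays at -13.8 to 43.8. The second held 16.4%, with untreated wild-type arrays at -19.2 to -7.08 and untreated knockout arrays at 6.55 to 18.4. The genotypes overlapped on it with TNBS, at -34.4 to 8.05 in wild type and -7.89 to 28.4 in the knockout. Of all values, 27.9% stood at the lowest value of the series, log2 2.17, called the floor here. The 3' minus 5' signal of the Gapdh control probe sets, a sign of RNA integrity, was lower in TNBS-treated knockout (0.943 ± 0.031, SD, n = 7) than in TNBS-treated wild-type arrays (1.06 ± 0.072, n = 6, exact permutation p = 0.00291, 0.035 after Benjamini-Hochberg adjustment over 12 tests). That of the beta-actin control probe sets did not pass there (1.12 ± 0.061 against 1.16 ± 0.112, exact permutation p = 0.423, adjusted 0.508) or in another comparison, so a difference in RNA integrity rests on Gapdh alone. The share of values at the floor was higher in untreated knockout (28.3% ± 0.16) than in untreated wild-type arrays (27.4% ± 0.34; n = 5 each, exact permutation p = 0.00794, adjusted 0.0476). The number of arrays limits the precision of every value below. Log2 fold changes are given with their standard error (SE).

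Tnfrsf12a itself was read first, as a check of the labels. It stood at 6.65 ± 0.52 (SD, n = 5) in untreated wild-type, 7.35 ± 0.51 (n = 6) in TNBS-treated wild-type, 4.11 ± 0.06 (n = 5) in untreated knockout and 4.06 ± 0.11 (n = 7) in TNBS-treated knockout colon, so no knockout array reached the lowest wild-type value of 5.86. The knockout level was 5.80-fold lower without TNBS (log2 fold change -2.54 ± 0.22, adjusted p = 2.2e-06) and 9.78-fold lower with TNBS (-3.29 ± 0.20, adjusted p = 9.3e-09). A second probe set differed by -2.67 and -3.31. Whether either probe set lies in the deleted part is not given in the sources used here, so a remaining signal in the knockout has no set meaning. In wild-type mice Tnfrsf12a rose with TNBS by 0.70 ± 0.21 (adjusted p = 0.029), a call that several alternative settings ended. The second probe set differed by 0.62 ± 0.21 there and did not pass (adjusted p = 0.0647 over all probe sets, where the first had 0.0391). In the knockout the first probe set differed by -0.05 ± 0.21 (adjusted p = 1), and its TNBS effects in the genotypes did not pass a test of their difference (-0.75 ± 0.30, adjusted p = 0.2). Tnfsf12, the gene of the ligand TWEAK, has no value here because its probe sets are annotated to several genes.

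**Figure D1:**
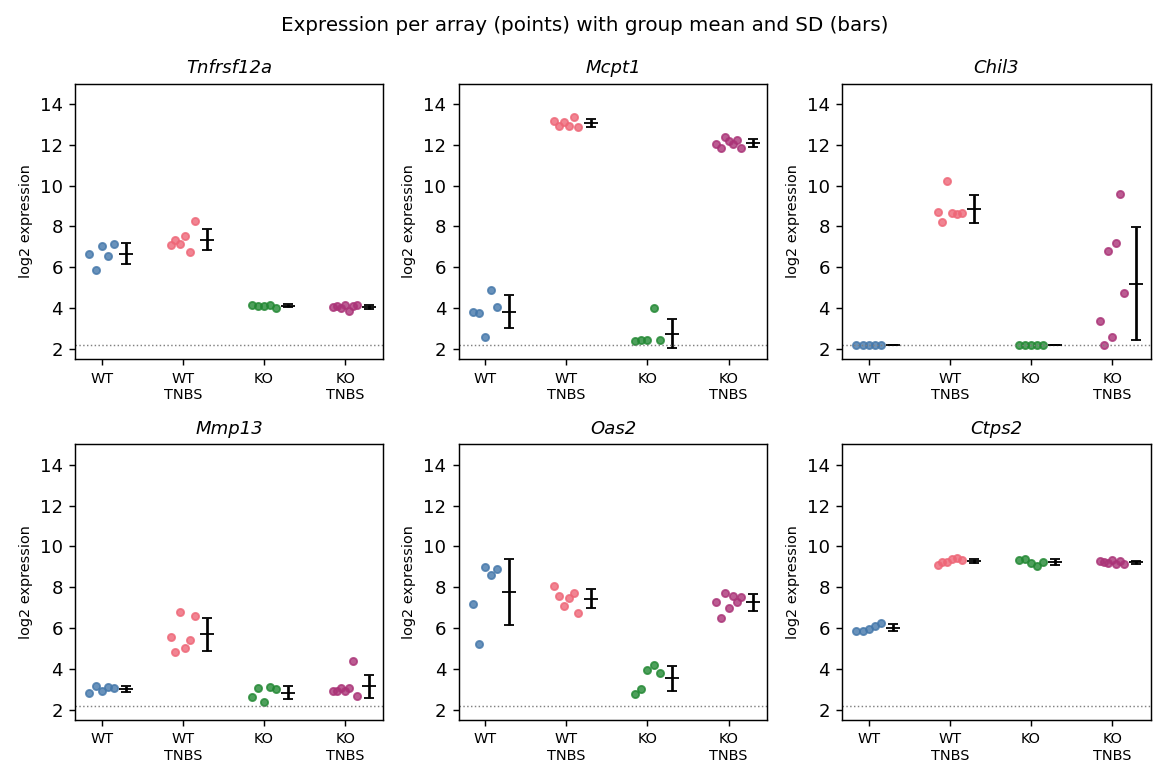
Log2 expression of 6 genes on each array, by group, with the group mean and SD as bars beside the points and the floor as a dotted line. Tnfrsf12a lay at 3.84 to 4.17 on the knockout arrays and at 5.86 to 8.25 on the wild-type arrays, and Ctps2 was low in untreated wild-type mice alone among the 4 groups.

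The comparison of TNBS-treated with untreated wild-type mice asks what chronic TNBS colitis changes in the colon. Mast cell proteases rose most. Mcpt1 and Mcpt2, granule proteases of mucosal mast cells, rose by 9.24 ± 0.31 and 9.36 ± 0.38 (adjusted p = 9.1e-14 and 1.7e-12) from untreated levels of 3.81 and 3.80. Rnase2a, of the ribonuclease family of eosinophils, rose by 8.07 ± 0.43, and Chil3, a chitinase-like protein of alternatively activated macrophages, rose by 6.68 ± 0.95 (adjusted p = 7.4e-05) from the floor on 4 of 5 untreated arrays to 8.85 ± 0.70 (SD, n = 6). Arntl, which encodes the clock factor BMAL1, fell by 2.46 ± 0.37, and the transporter genes Slc30a10 and Slc34a2 fell by 2.04 ± 0.26 and 1.33 ± 0.36. Of 18194 genes, 1858 rose and 1140 fell at an adjusted p under 0.05, and 486 of these changed by at least 1 on the log2 scale, 447 upwards and 39 downwards.

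Among the gene lists fixed before the data were examined, the mast cell list had 11 measured members, of which 9 rose and 2 did not pass (9 adjusted over the list alone; camera adjusted p = 2.9e-20, adjusted p = 0.0048 with an estimated correlation). Cpa3, mast cell carboxypeptidase, rose by 6.00 ± 0.22 and the chymase gene Mcpt4 by 4.96 ± 0.25. The list of type 2 cytokines and their targets had 19 measured members, of which 13 rose and 6 did not pass (14 adjusted over the list alone; adjusted p = 3.2e-10, adjusted p = 0.013 with an estimated correlation). Arg1, arginase 1, rose by 5.09 ± 0.71, Retnla by 2.77 ± 0.29, the goblet cell product Retnlb by 1.79 ± 0.17 and the eotaxin gene Ccl24 by 1.60 ± 0.15. Of 6 measured eosinophil markers 2 rose (2 adjusted over the list alone), Alox15 by 2.27 ± 0.23 and Siglecf by 1.69 ± 0.25, and 2 others were at the floor on all arrays (adjusted p = 0.024, adjusted p = 0.178 with an estimated correlation).

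Other leukocyte markers rose as well. Of 15 monocyte and macrophage markers 12 rose and 3 did not pass (13 adjusted over the list alone; adjusted p = 4.3e-11, adjusted p = 0.153 with an estimated correlation). Among them were the chemokine receptor Ccr2 (2.10 ± 0.23), the mannose receptor Mrc1 (1.30 ± 0.19) and Csf1r (1.14 ± 0.18). Of 16 T cell markers 10 rose and 6 did not pass (12 adjusted over the list alone; adjusted p = 3.4e-06, adjusted p = 0.178 with an estimated correlation). The costimulator Icos rose by 2.35 ± 0.34 and Cd3d by 1.16 ± 0.23. Of 17 B cell and follicle markers 7 rose and 10 did not pass (16 adjusted over the list alone; adjusted p = 4.5e-06, adjusted p = 0.324 with an estimated correlation). The homing receptor Ccr7 rose by 1.47 ± 0.25. Of 10 plasma cell markers 7 rose and 3 did not pass (7 adjusted over the list alone; adjusted p = 4.5e-06, adjusted p = 0.173 with an estimated correlation). Prdm1, which encodes Blimp-1, rose by 1.01 ± 0.13. Among 9 markers of cytotoxic lymphocytes 5 rose, 1 fell and 3 did not pass (5 and 1 adjusted over the list alone; adjusted p = 0.0025, adjusted p = 0.178 with an estimated correlation). The granzyme genes Gzma and Gzmb rose by 2.58 ± 0.32 and 1.95 ± 0.28. The marker that fell was perforin (Prf1, -0.29, adjusted p = 0.0084), named here after its value was seen.

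Chemokine and matrix genes formed a further set of changes. Of 21 acute inflammatory cytokines and chemokines 7 rose and 14 did not pass (10 adjusted over the list alone; adjusted p = 1.5e-06, adjusted p = 0.179 with an estimated correlation). Among them were the monocyte attractants Ccl8 (3.49 ± 0.42), Ccl7 (2.84 ± 0.33) and Ccl2 (1.49 ± 0.22). Of 22 genes of the interferon gamma response 10 rose and 12 did not pass (10 adjusted over the list alone; adjusted p = 7.2e-06, adjusted p = 0.293 with an estimated correlation). Cxcl10 rose by 2.01 ± 0.29 and Cxcl9 by 1.96 ± 0.35. Collagens and other genes of fibrotic matrix rose in 19 of 26 cases, and 7 did not pass (21 adjusted over the list alone; adjusted p = 3.5e-14, adjusted p = 0.178 with an estimated correlation). Fibronectin (Fn1) rose by 1.10 ± 0.15 and Col5a2 by 0.98 ± 0.14. Of 17 metalloproteinases and their inhibitors 11 rose and 6 did not pass (12 adjusted over the list alone; adjusted p = 3.7e-09, adjusted p = 0.12 with an estimated correlation). The gelatinase gene Mmp9 rose by 4.15 ± 0.41, the collagenase gene Mmp13 by 2.68 ± 0.33 and Mmp10 by 2.68 ± 0.40. Of 18 TGF-beta and profibrotic factors 7 rose, 1 fell and 10 did not pass (9 and 1 adjusted over the list alone; adjusted p = 0.00065, adjusted p = 0.262 with an estimated correlation). Igf1 rose by 1.55 ± 0.20 and Tgfb1, at low signal, by 1.23 ± 0.17. The factor that fell was the inhibitory Smad7 (-0.30, adjusted p = 0.0499), named here after its value was seen. Of 17 genes of the TWEAK and NF-kappaB pathway 8 rose and 9 did not pass (10 adjusted over the list alone; adjusted p = 4.5e-06, adjusted p = 0.0906 with an estimated correlation). The adhesion molecules Vcam1 and Icam1 rose by 1.39 ± 0.20 and 1.11 ± 0.18.

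Lists of epithelial genes moved in both directions. Of 22 markers of absorptive colonocytes 7 fell and 15 did not pass (8 fell and 1 rose adjusted over the list alone; adjusted p = 0.00016, adjusted p = 0.179 with an estimated correlation). Slc51b, of a bile acid exporter, changed by -0.80 ± 0.23. Of 16 genes of xenobiotic and bile acid handling 6 fell and 10 did not pass (6 adjusted over the list alone; adjusted p = 0.00054, adjusted p = 0.29 with an estimated correlation). The sulfotransferase gene Sult1c2 changed by -0.87 ± 0.12. Among 13 genes of epithelial junctions 4 fell, 1 rose and 8 did not pass (5 and 1 adjusted over the list alone; adjusted p = 0.01, adjusted p = 0.12 with an estimated correlation). The claudin gene Cldn8 fell by 1.26 ± 0.18 and occludin (Ocln) fell by 0.74 ± 0.12, whereas Cldn4 rose by 1.57 ± 0.34. Of 10 genes of wound and regenerating epithelium 5 rose and 5 did not pass (5 adjusted over the list alone; adjusted p = 0.012, adjusted p = 0.232 with an estimated correlation). Sprr1a, of the cornified envelope, rose by 1.41 ± 0.39 and the annexin gene Anxa3 by 0.46 ± 0.11. The list of antimicrobial and epithelial defence did not pass (adjusted p = 0.15, adjusted p = 0.44 with an estimated correlation), though it did by fry (adjusted p = 0.0083) and with arrays centred on their medians (adjusted p = 0.038). Of its 18 genes 6 rose, 2 fell and 10 did not pass (6 and 3 adjusted over the list alone), with Ang4 up by 3.28 ± 0.31 and the protease inhibitor gene Slpi by 2.88 ± 0.43. The genes that fell were the serum amyloid genes Saa1 (-0.18, adjusted p = 0.011) and Saa2 (-0.38, adjusted p = 0.041), named here after their values were seen. Of 15 circadian clock genes 7 rose, 3 fell and 5 did not pass (10 and 4 adjusted over the list alone; adjusted p = 0.049, adjusted p = 0.424 with an estimated correlation), with Dbp up by 3.21 ± 0.55 and Npas2 down, at -1.72 ± 0.26. The time of day of tissue collection is not given in the sources used here.

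Lists of other tissues were tested as well. Of 14 squamous epithelium and skin markers 6 rose and 8 did not pass (12 adjusted over the list alone; adjusted p = 6e-05, adjusted p = 0.349 with an estimated correlation). The basal keratin Krt14 rose by 4.11 ± 0.82. The mean of the list was 4.40 ± 0.88 (SD, n = 5) without and 6.85 ± 1.22 (n = 6) with TNBS (exact permutation p = 0.0108, 0.0433 after adjustment over 8 tests). Among 8 pancreas genes only Clps, colipase, passed (1 adjusted over the list alone), at 2.34 ± 0.17 (list adjusted p = 0.0064, adjusted p = 0.426 with an estimated correlation). Pnliprp2, a pancreatic lipase-related gene outside that list, rose by 6.51 ± 0.28 (adjusted p = 3.2e-12), and by 4.98 ± 0.27 in the knockout (adjusted p = 3.8e-10). In all, 32 of the 41 lists passed, 25 upwards and 7 downwards, and 2 of them with an estimated correlation. With the squamous mean as a covariate, an alternative added after seeing the data, 1231 genes were called in place of 2998, and the wound, clock, squamous and pancreas lists were not called. Centring the arrays on their medians moved the share of called genes that rose from 62.0% to 43.4% and ended the calls of the eosinophil and junction lists. The clock list lost its call under 16 of 24 alternatives, 7 of which left out 1 array (adjusted p = 0.0524 to 0.131 in those). With values below log2 5 set to 5, likewise added, Ccl24, Alox15, Ccr7, Ccl7, Mmp13, Tgfb1, Smad7 and Cldn4 were no longer called, nor were the eosinophil and clock lists.

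**Figure D2:**
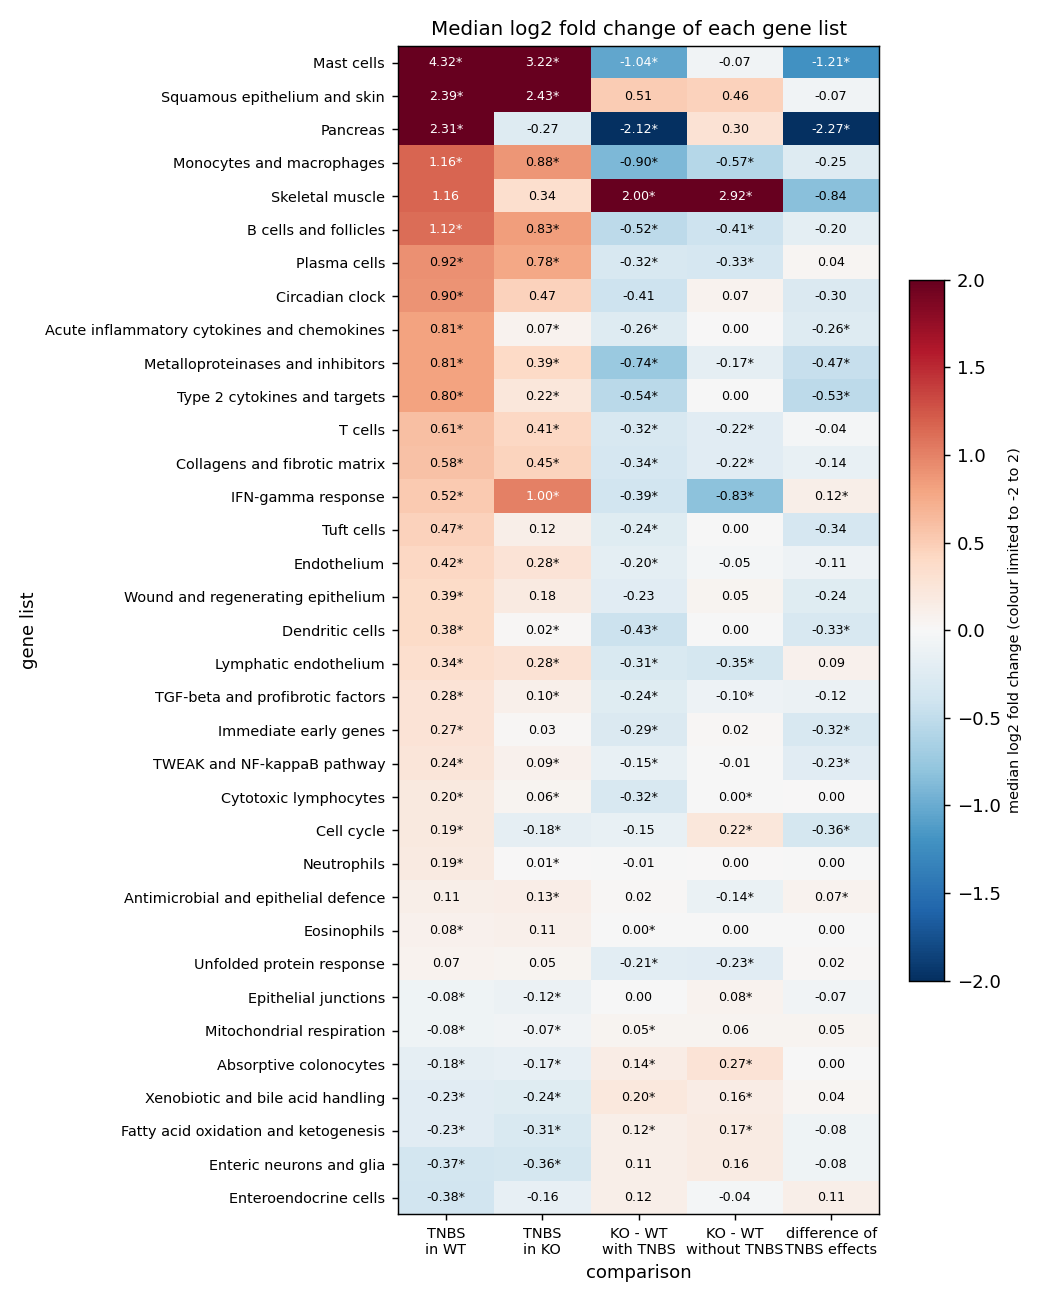
Median log2 fold change of the members of each gene list (rows of the map) that passed in at least 1 of the 5 comparisons (columns of the map), with an asterisk where the camera adjusted p was under 0.05 at the preset correlation. The colour scale ends at -2 and 2. The mast cell list had medians of 4.32 and 3.22 under TNBS in wild type and knockout, and the squamous list 2.39 and 2.43. The skeletal muscle list had medians of 2.00 and 2.92 between the genotypes with and without TNBS. For the pancreas list they were 2.31 under TNBS in wild type, -2.12 between the genotypes with TNBS and -2.27 for the difference of TNBS effects.

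The same question was put to mice without Fn14. Mast cell proteases again rose most with TNBS, Mcpt1 by 9.33 ± 0.30 and Mcpt2 by 9.05 ± 0.37 (adjusted p = 7.9e-14 and 3.4e-12). Rnase2a rose by 5.36 ± 0.42, the chemokine gene Ccl8 by 4.69 ± 0.41, Ang4, an antimicrobial ribonuclease of the gut epithelium, by 4.12 ± 0.30, and the epithelial protease inhibitor Spink5 by 4.05 ± 0.54. The apolipoprotein genes Apoa1, Apoa4 and Apoc3 fell by 5.63 ± 1.19, 5.52 ± 1.05 and 4.81 ± 1.01 from variable untreated levels (Apoa1 7.85 ± 2.64, SD, n = 5) to 2.22 ± 0.04 (n = 7). Of 18194 genes, 743 rose and 813 fell, and 262 of these changed by at least 1 on the log2 scale, 238 upwards and 24 downwards. Which direction held more calls depended on the scaling, with 47.8% of called genes rising as deposited, 53.9% after quantile normalization and 41.3% after centring on medians.

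Of the 11 mast cell markers 8 rose, 1 fell and 2 did not pass (9 and 1 adjusted over the list alone; adjusted p = 1.1e-21, adjusted p = 0.0048 with an estimated correlation). Cpa3 rose by 4.63 ± 0.21 and Mcpt4 by 3.33 ± 0.24. The marker that fell was Kit (-0.48 ± 0.11, adjusted p = 0.012), named here after its value was seen. Interstitial cells of Cajal express it too. Of 19 type 2 genes 6 rose and 13 did not pass (7 adjusted over the list alone; adjusted p = 1.2e-06, adjusted p = 0.0663 with an estimated correlation). Retnlb rose by 1.78 ± 0.17 and Retnla by 1.27 ± 0.28. Of 22 interferon gamma response genes 13 rose and 9 did not pass (16 adjusted over the list alone; adjusted p = 3.5e-14, adjusted p = 0.141 with an estimated correlation). Cxcl9 rose by 2.55 ± 0.34, Cxcl10 by 2.05 ± 0.28 and Gbp3, a guanylate-binding protein, by 1.78 ± 0.29. Monocyte and macrophage markers rose in 10 of 15 cases and 5 did not pass (12 adjusted over the list alone; adjusted p = 4.8e-12, adjusted p = 0.137 with an estimated correlation). Ccr2 rose by 1.73 ± 0.23 and the complement gene C1qb by 0.88 ± 0.18. Of 10 plasma cell markers 8 rose and 2 did not pass (9 adjusted over the list alone; adjusted p = 1.6e-10, adjusted p = 0.0663 with an estimated correlation). Mzb1 rose by 1.78 ± 0.28. Of 9 cytotoxic lymphocyte markers 3 rose and 6 did not pass (4 adjusted over the list alone; adjusted p = 9.6e-05, adjusted p = 0.0953 with an estimated correlation). Gzma rose by 2.98 ± 0.31 and Gzmb by 2.55 ± 0.27.

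In the knockout 16 of 26 collagen and matrix genes rose and 10 did not pass (17 adjusted over the list alone; adjusted p = 2.75e-17, adjusted p = 0.141 with an estimated correlation). Col1a1, of type I collagen, rose by 0.93 ± 0.11. Of 17 metalloproteinases and inhibitors 4 rose and 13 did not pass (7 adjusted over the list alone; adjusted p = 4.3e-05, adjusted p = 0.247 with an estimated correlation). Mmp9 rose by 1.72 ± 0.39 and the inhibitor gene Timp1 by 1.74 ± 0.39. Genes of antimicrobial and epithelial defence rose in 5 of 18 cases and 13 did not pass (7 adjusted over the list alone; adjusted p = 4.3e-05, adjusted p = 0.077 with an estimated correlation). The phospholipase gene Pla2g2a rose by 1.95 ± 0.23. Of 13 epithelial junction genes 5 fell and 8 did not pass (6 adjusted over the list alone; adjusted p = 0.00029, adjusted p = 0.0317 with an estimated correlation). Cingulin (Cgn) changed by -0.27 ± 0.05 and Cldn8 by -0.63 ± 0.17. Of 13 genes of fatty acid oxidation and ketogenesis 5 fell and 8 did not pass (10 adjusted over the list alone; adjusted p = 7.2e-06, adjusted p = 0.265 with an estimated correlation). Ehhadh, of peroxisomal beta-oxidation, changed by -0.55 ± 0.13. Squamous markers rose in 3 of 14 cases and 11 did not pass (11 adjusted over the list alone; adjusted p = 1.1e-07, adjusted p = 0.256 with an estimated correlation). Krt14 rose by 3.21 ± 0.80. Their mean was 5.04 ± 1.37 (SD, n = 5) without and 7.44 ± 1.61 (n = 7) with TNBS (exact permutation p = 0.0265, adjusted 0.0559). In all, 26 of 41 lists passed, 19 upwards and 7 downwards, 2 of them with an estimated correlation. The count of 1556 genes fell to 1014 without untreated knockout replicate 3, to 856 when the 2 groups were fitted alone, and to 568 and 813 with the squamous mean or the Gapdh 3' minus 5' signal as covariate, both added after seeing the data. Mmp9, Timp1, Cldn8, Ehhadh, Krt14 and Kit were not called with either covariate, nor were the metalloproteinase and squamous lists with the squamous mean.

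The comparison of knockout with wild-type mice under TNBS asks whether loss of Fn14 alters the colon with chronic colitis. Among the genes lower without Fn14 were 10 of 17 metalloproteinases and inhibitors and 8 of 19 type 2 genes (list adjusted p = 0.12 and adjusted p = 0.0317 with an estimated correlation). Mmp13 and Mmp9 fell by 2.56 ± 0.30 and 2.15 ± 0.37 (adjusted p = 3.7e-05 and 0.001), Ch25h, which makes the leukocyte attractant precursor 25-hydroxycholesterol, by 2.00 ± 0.14 (adjusted p = 6.2e-08), the lipoxygenase gene Alox15 by 2.16 ± 0.21 and the T cell costimulator Icos by 2.00 ± 0.31. Atrnl1 was higher by 2.37 ± 0.22, the magnesium channel gene Trpm6 by 1.32 ± 0.17 and the carboxylesterase gene Ces2b by 1.17 ± 0.18. Of 18194 genes, 679 were higher and 1223 lower in the knockout, and 196 of these differed by at least 1 on the log2 scale, 21 higher and 175 lower.

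Type 2 genes were lower in 8 of 19 cases and 11 did not pass (12 adjusted over the list alone; adjusted p = 5.3e-08, adjusted p = 0.0317 with an estimated correlation). The eotaxin genes Ccl11 and Ccl24 differed by -1.52 ± 0.22 and -1.47 ± 0.14, Retnla by -1.49 ± 0.26 and Ccl22 by -0.91 ± 0.16. Of 11 mast cell markers 7 were lower and 4 did not pass (9 adjusted over the list alone; adjusted p = 5e-09, adjusted p = 0.071 with an estimated correlation). Fcer1a, a chain of the IgE receptor, differed by -2.00 ± 0.30, Cpa3 by -1.75 ± 0.20 and Mcpt4 by -1.71 ± 0.23. Eosinophil markers were lower in 2 of 6 cases (2 adjusted over the list alone), namely Alox15 and Siglecf (-1.01 ± 0.23; list adjusted p = 0.0495, adjusted p = 0.232 with an estimated correlation). Of 15 monocyte and macrophage markers 11 were lower and 4 did not pass (12 adjusted over the list alone; adjusted p = 1.8e-09, adjusted p = 0.178 with an estimated correlation). The scavenger receptor Msr1 differed by -1.26 ± 0.22, Mrc1 by -1.08 ± 0.18 and C1qa by -0.96 ± 0.20. T cell markers were lower in 5 of 16 cases and 11 did not pass (6 adjusted over the list alone; adjusted p = 0.00031, adjusted p = 0.262 with an estimated correlation). Among 9 cytotoxic lymphocyte markers 2 were lower, 1 higher and 6 did not pass (4 and 1 adjusted over the list alone; adjusted p = 0.027, adjusted p = 0.267 with an estimated correlation). Gzmb differed by -1.93 ± 0.25 and Gzma by -1.85 ± 0.30. The marker that was higher was Prf1 (0.34, adjusted p = 0.0025), likewise named after its value was seen.

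Of 17 metalloproteinases and inhibitors 10 were lower and 7 did not pass (12 adjusted over the list alone; adjusted p = 3.5e-09, adjusted p = 0.12 with an estimated correlation). Mmp3 differed by -1.49 ± 0.26 and Adam8 by -1.37 ± 0.21. Collagen and matrix genes were lower in 10 of 26 cases and 16 did not pass (21 adjusted over the list alone; adjusted p = 4.5e-09, adjusted p = 0.253 with an estimated correlation). Fn1 differed by -0.61 ± 0.14 and tenascin C (Tnc) by -0.48 ± 0.10. Of 18 TGF-beta and profibrotic factors 8 were lower and 10 did not pass (9 adjusted over the list alone; adjusted p = 8.3e-05, adjusted p = 0.229 with an estimated correlation). Tgfb1 differed by -1.10 ± 0.15 and Pdgfra by -0.42 ± 0.07. Of 21 acute inflammatory genes 7 were lower and 14 did not pass (7 adjusted over the list alone; adjusted p = 1.6e-05, adjusted p = 0.232 with an estimated correlation). Interleukin 1 beta (Il1b) differed by -2.14 ± 0.41, Ccl7 by -1.78 ± 0.30 and Ccl2 by -1.23 ± 0.20. Of 17 genes of the TWEAK and NF-kappaB pathway 5 were lower and 12 did not pass (6 adjusted over the list alone; adjusted p = 0.001, adjusted p = 0.183 with an estimated correlation). Vcam1 differed by -1.23 ± 0.18, Cd40 by -0.98 ± 0.24 and Icam1 by -0.71 ± 0.17.

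Some epithelial genes were higher in the TNBS-treated knockout. Absorptive colonocyte markers were higher in 4 of 22 cases and 18 did not pass (4 adjusted over the list alone; adjusted p = 0.00013, adjusted p = 0.178 with an estimated correlation). Hsd11b2, which inactivates glucocorticoids, differed by 0.62 ± 0.10. Of 16 xenobiotic and bile acid genes 1 was higher and 15 did not pass (7 adjusted over the list alone; adjusted p = 0.00024, adjusted p = 0.279 with an estimated correlation), namely Sult1c2 at 0.89 ± 0.11. Of 10 skeletal muscle markers 0 passed limma over all genes, with 8 higher at an unadjusted p under 0.05 (7 higher adjusted over the list alone). The list passed (median 2.00, adjusted p = 2.8e-05, adjusted p = 0.264 with an estimated correlation, fry adjusted p = 0.0194). Its mean was 6.89 ± 1.16 (SD, n = 7) in knockout and 4.93 ± 1.53 (n = 6) in wild-type mice (exact permutation p = 0.028, adjusted 0.0559). Pnliprp1, a pancreatic lipase-related gene outside the pancreas list, was lower by a log2 fold change of -3.09 ± 0.66 (adjusted p = 0.0048), the largest fall by the naming rule after Tnfrsf12a. Of the 8 genes of the pancreas list 1 was lower, Clps at -0.82 ± 0.16, which lies within 20 Mb of Tnfrsf12a, and 7 did not pass, with 6 lower at an unadjusted p under 0.05 (1 lower adjusted over the list alone). The list passed (median -2.12, adjusted p = 0.0085, adjusted p = 0.44 with an estimated correlation), but not by fry (adjusted p = 0.0547) or without TNBS-treated wild-type replicate 6 (median -1.01, adjusted p = 0.0538). In all, 26 of 41 lists passed, 5 upwards and 21 downwards, 1 of them with an estimated correlation. With the Gapdh 3' minus 5' signal as covariate, added after seeing the data, 738 genes were called in place of 1902, and Retnla, Siglecf, Prf1, Fn1, Cd40 and Clps were not among them. The eosinophil and cytotoxic lists lost their calls with that covariate or the muscle mean, which also ended the call of the muscle list. The eosinophil list lost it under 15 of 25 alternatives, 8 of which left out 1 array (adjusted p = 0.0501 to 0.0917 in those), and the cytotoxic list also without TNBS-treated knockout replicate 5 (adjusted p = 0.0526) and without the dimmer probe sets (adjusted p = 0.0545). With values below log2 5 set to 5, likewise added, Alox15, Ccl24, Ccl22, Tgfb1 and Ccl7 were not called, nor were the eosinophil and cytotoxic lists.

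Knockout and wild-type mice were also compared without TNBS. Genes known as interferon-stimulated were among the largest falls, and 3 of 10 skeletal muscle markers were higher (list adjusted p = 0.223 with an estimated correlation). No list of type I interferon-stimulated genes was fixed before the data were examined. Oas2, an oligoadenylate synthetase of the antiviral response, was lower by a log2 fold change of -4.24 ± 0.53 (adjusted p = 0.00019), with Usp18 at -3.72 ± 0.47, Ifit3 at -3.23 ± 0.45 and Oasl2 at -3.00 ± 0.30. Tnnt3 and Tnni2, troponins of fast skeletal muscle, and skeletal actin (Acta1) were higher by 4.22 ± 1.10, 3.81 ± 1.00 and 3.28 ± 0.79 (adjusted p = 0.032, 0.034 and 0.022). S100g, the calcium-binding protein calbindin-D9k, and Ctps2, a CTP synthase, were higher by 4.29 ± 0.30 and 3.22 ± 0.08 (adjusted p = 8.6e-08 and 3.1e-16). Of 18194 genes, 531 were higher and 348 lower in the knockout, and 102 of these differed by at least 1 on the log2 scale, 26 higher and 76 lower.

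Of 22 interferon gamma response genes 8 were lower and 14 did not pass (12 adjusted over the list alone; adjusted p = 1.5e-08, adjusted p = 0.237 with an estimated correlation). Gbp3 differed by -1.81 ± 0.32, Cxcl9 by -1.75 ± 0.36 and the immunoproteasome gene Psmb9 by -1.13 ± 0.21. Psmb9 lies among the H2 genes within 20 Mb of Tnfrsf12a and was lower with TNBS too (-0.77 ± 0.18). Among 9 cytotoxic lymphocyte markers 2 were lower and 7 did not pass (2 adjusted over the list alone; adjusted p = 0.015, adjusted p = 0.251 with an estimated correlation), Gzmb at -2.53 ± 0.29 and Gzma at -2.25 ± 0.34. Monocyte and macrophage markers were lower in 1 of 15 cases, the Fc receptor gene Fcgr1 at -1.31 ± 0.35, and 14 did not pass (10 adjusted over the list alone; adjusted p = 2e-06, adjusted p = 0.251 with an estimated correlation). Of 26 collagen and matrix genes 1 was lower, Col1a1 at -0.52 ± 0.12, and 25 did not pass (1 adjusted over the list alone; adjusted p = 3.4e-06, adjusted p = 0.324 with an estimated correlation). Of 14 genes of the unfolded protein response 2 were lower and 12 did not pass (5 adjusted over the list alone; adjusted p = 1.6e-05, adjusted p = 0.251 with an estimated correlation), Pdia4 at -0.79 ± 0.22 and Dnajb9 at -0.29 ± 0.08. Absorptive colonocyte markers were higher in 4 of 22 cases and 18 did not pass (9 higher and 1 lower adjusted over the list alone; adjusted p = 0.00165, adjusted p = 0.251 with an estimated correlation). The phosphate transporter Slc20a1 differed by 0.59 ± 0.13.

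Of 10 skeletal muscle markers 3 were higher and 7 did not pass (10 adjusted over the list alone; adjusted p = 5.9e-07, adjusted p = 0.223 with an estimated correlation). Their mean was 6.68 ± 0.91 (SD, n = 5) in untreated knockout and 3.89 ± 0.89 (n = 5) in untreated wild-type mice, with no overlap (exact permutation p = 0.00794, the smallest that 5 against 5 arrays can give; adjusted 0.0433). In all, 18 of 41 lists passed, 6 upwards and 12 downwards, 0 of them by camera with an estimated correlation (2 lists at an unadjusted p under 0.05) and 8 by fry. With the muscle mean as a covariate, added after seeing the data, 104 genes were called in place of 879, without Tnnt3, Tnni2, Acta1, Cxcl9, Psmb9, Fcgr1, Col1a1, Pdia4, Dnajb9 and Slc20a1 or the cytotoxic and muscle lists, and 288 were called when the 2 groups were fitted alone. The cytotoxic list was not called with values below log2 5 set to 5, and the collagen list was not by fry (adjusted p = 0.0959). Without wild-type replicate 1 the count was 458 and without knockout replicate 4 it was 484. Quantile normalization or centring on medians moved the share of called genes that were higher from 60.4% to 49.7% or 41.6%.

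The last comparison asks whether the TNBS effect differs between the genotypes. Genes known as interferon-stimulated were among the largest positive differences: Oas2 differed by 4.06 ± 0.71 (adjusted p = 0.0076) and Ifit3 by 2.97 ± 0.60 (adjusted p = 0.015). Oas2 stood at 7.77 ± 1.60 (SD, n = 5) and 7.43 ± 0.47 (n = 6) in wild-type mice without and with TNBS, and at 3.53 ± 0.62 (n = 5) and 7.26 ± 0.41 (n = 7) in the knockout. S100g and Ctps2 differed by -3.83 ± 0.40 and -3.28 ± 0.10, both low in untreated wild-type mice. Rnase2a and Mmp9 rose less with TNBS in the knockout than in wild type, with differences of -2.72 ± 0.60 and -2.43 ± 0.56. Mmp13 and Alox15 rose in wild type and did not pass in the knockout (0.30 ± 0.32 and 0.22 ± 0.22, adjusted p = 0.697 and 0.663), with differences of -2.38 ± 0.46 and -2.04 ± 0.32. In all 113 genes had a positive and 250 a negative difference.

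Mast cell markers differed in 4 of 11 cases and 7 did not pass (6 adjusted over the list alone; adjusted p = 2.8e-05, adjusted p = 0.178 with an estimated correlation). Fcer1a differed by -2.03 ± 0.45 (adjusted p = 0.023), Mcpt4 by -1.63 ± 0.35 and Cpa3 by -1.36 ± 0.30. Of 17 metalloproteinases and inhibitors 2 differed and 15 did not pass (3 adjusted over the list alone; adjusted p = 0.00054, adjusted p = 0.283 with an estimated correlation). Of 19 type 2 genes 1 differed, Ccl24 at -1.47 ± 0.21, and 18 did not pass (5 adjusted over the list alone; adjusted p = 0.00088, adjusted p = 0.178 with an estimated correlation). Of 13 immediate early genes 1 differed, the transcription factor gene Egr1 at -1.83 ± 0.30, and 12 did not pass (3 adjusted over the list alone; adjusted p = 0.00465, adjusted p = 0.283 with an estimated correlation). Of 20 cell cycle genes 0 passed limma over all genes, with 8 lower at an unadjusted p under 0.05 (1 lower adjusted over the list alone). The list passed with a median of -0.36 (adjusted p = 0.00019, adjusted p = 0.324 with an estimated correlation, fry adjusted p = 0.0427), and Mcm7 had the smallest p (-0.56 ± 0.16, adjusted p = 0.074). Acute inflammatory genes differed in 1 of 21 cases, Ccl7 at -1.81 ± 0.46, and 20 did not pass (2 adjusted over the list alone; adjusted p = 0.019, adjusted p = 0.484 with an estimated correlation, fry adjusted p = 0.11, adjusted p = 0.356 without the dimmer probe sets, and adjusted p = 0.0651 without TNBS-treated wild-type replicate 6). In all, 11 of 41 lists passed, 2 upwards and 9 downwards, 0 of them by camera with an estimated correlation (2 lists at an unadjusted p under 0.05) and 8 by fry. The count of 363 genes fell to 213 without untreated knockout replicate 4 and to 238 without untreated wild-type replicate 1. Quantile normalization or centring on medians moved the share of positive differences from 31.1% to 41.6% or 41.3%. Fcer1a, Mcpt4, Cpa3 and Ccl7 were not called with the Gapdh 3' minus 5' signal as covariate, and Oas2, Mmp13, Alox15, Ccl24, Ccl7 and the acute inflammatory list were not called with values below log2 5 set to 5.

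Across all 18194 genes, the TNBS effects in wild type and knockout, which share no arrays, correlated with a Pearson r of 0.741 and a Spearman rho of 0.410 (genes are not independent replicates). Of the genes called in both, 732 changed in the same direction and 17 did not, where 127 would be called in the same direction if the 2 sets of calls were independent. The 2 genotype comparisons share no arrays either and correlated at r = 0.438, with 169 genes called in the same direction against 43.2 for independent calls. The lists of goblet cells, smooth muscle, crypt base and stem cells, adipocytes, the Th17 and IL-22 axis and sex-linked genes passed in 0 of 30 tests by camera, 0 also at an unadjusted p under 0.05, and in 2 by fry.

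**Figure D3:**
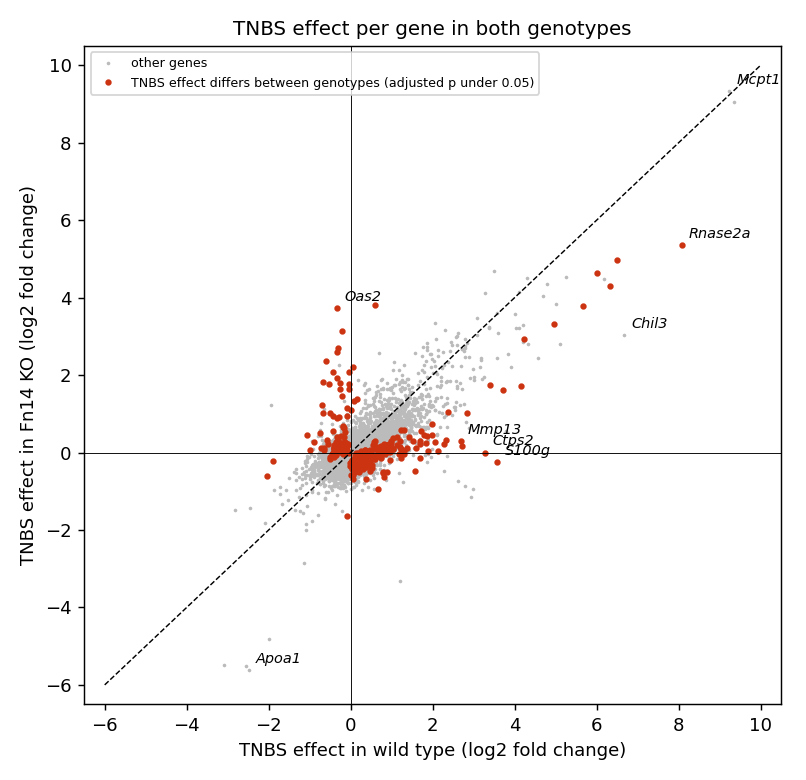
Log2 fold change with TNBS per gene in wild type (horizontal) against Fn14 knockout (vertical), with the line of equal effects dashed and the 363 genes whose effects differed between genotypes in red. Most such points with a rise in wild type lie below the line, and Oas2, an interferon-stimulated gene, lies at -0.34 in wild type and 3.72 in the knockout.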

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

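The tests of the interferon-stimulated genes and of Ctps2 and S100g below were chosen after the results were seen; the splits of the arrays were planned. Interferon-stimulated genes were among the largest positive differences of the TNBS effect between genotypes, such as Oas2 (4.06), Usp18 (3.35), Ifit3 (2.97) and Oasl2 (2.92). Over 28 measured type I interferon-stimulated genes, a list written after these were seen, 26 were lower in untreated knockout than untreated wild-type mice, 26 rose with TNBS in the knockout, and 0 passed limma for TNBS in wild type, where 4 had an unadjusted p under 0.05. The mean of the list differed by -2.11 between the untreated groups (95% interval -2.76 to -1.47) and by -0.22 between the TNBS-treated groups (-0.79 to 0.35). This restates the observation for which the list was written. Untreated wild-type arrays spread widely in that mean, from 8.47 to 10.6 (SD 0.88), against 7.41 to 8.04 (SD 0.28) in the untreated knockout. For the difference of TNBS effects 17 of the 28 genes passed limma over all genes, an adjustment that does not rest on the list. For those 17 genes this argues against an effect of Fn14 loss that is the same with and without TNBS. Their number adds no further support, since the list was written from these arrays and genes that vary together are not independent. The mean of 38 leukocyte markers was lower in the untreated knockout too, at -0.64 against untreated wild type (95% interval -1.08 to -0.20). Relative to these markers the mean of the list differed by -1.47 (-2.27 to -0.67). This argues against fewer leukocytes as the whole cause only if the list falls as much as the markers on the log2 scale. A loss of particular leukocytes need not follow that and was not tested. Skeletal muscle in the samples is argued against as the whole cause, since the difference with the muscle mean as a covariate was -2.11 (-2.99 to -1.23). An effect of genotype that is absent under TNBS and an exposure that differed between the untreated groups stay open, and neither was tested.

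Ctps2 and S100g were low in untreated wild-type mice and higher in the other groups, so that the TNBS effect differed between genotypes by -3.28 and -3.83. The genes were picked for this, so the bounds that follow restate it, but both passed limma over all genes for TNBS in wild type (smaller of the lower 95% bounds 2.97), a rise that loss of Fn14 alone does not give. Both also passed over all genes for untreated knockout against untreated wild-type mice (smaller lower bound 3.05), a difference that TNBS alone does not give. Genes that differed between untreated wild-type mice and the mean of the other groups were over-represented within 20 Mb of Ctps2 on the X chromosome. Ctps2 and S100g were left out (18 of 100 against 1374 of 17930 elsewhere, odds ratio 2.64, 95% interval 1.49 to 4.46, one-sided Fisher's exact p = 0.00059). Genes changed by TNBS alone can pass that contrast too, so it does not pick out genes particular to untreated wild-type mice. An inherited stretch that differs in these mice, for example from another breeding source, is a candidate explanation, and no genotypes were tested.

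Other named genes whose TNBS effect differed between genotypes were Alox15 (-2.04), Ccl24 (-1.47), Ccl7 (-1.81), Ch25h (-1.44), Cldn4 (-2.05), Cpa3 (-1.36), Egr1 (-1.83), Fcer1a (-2.03), Mcpt4 (-1.63), Mmp13 (-2.38), Mmp9 (-2.43), Rnase2a (-2.72), Siglecf (-1.48) and Tgfb1 (-1.14) with negative differences, and Atrnl1 (1.67) and Slc30a10 (1.43) with positive differences. Lists that passed the same test had median differences of -1.21 (mast cells), -0.53 (type 2 genes), -0.26 (acute inflammatory genes), -0.47 (metalloproteinases), -0.23 (TWEAK and NF-kappaB pathway), -2.27 (pancreas), -0.36 (cell cycle), -0.32 (immediate early genes), -0.33 (dendritic cells), 0.12 (interferon gamma response) and 0.068 (antimicrobial defence). Of these 11 lists 0 passed by camera with an estimated correlation, where the adjusted p was 0.178 to 0.642, among them 0.262 for the TWEAK and NF-kappaB pathway, 0.515 for pancreas, 0.274 for dendritic cells, 0.642 for the interferon gamma response and 0.264 for antimicrobial defence. No member of these 5 lists passed limma over all genes (5 of 17, 1 of 8, 4 of 10, 5 of 22 and 1 of 18 at an unadjusted p under 0.05; 0 of each adjusted over the list alone), and fry adjusted p was 0.0155, 0.163, 0.0209, 0.609 and 0.207.

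Single arrays far from the rest of their group were found in 34 of 329 groups of values tested. These covered 107 of the named genes, array measures, and the means of the skeletal muscle and squamous lists. Chance gives about 1 in 20 for normally distributed values, which values at the floor are not, and genes that vary together are not independent. Near the floor a small gap is enough. Examples are Fcer1a in untreated knockout (2.35, next 2.17), and Apoc3 (2.17, next 2.29) and Apoa4 (2.32, next 2.29) in TNBS-treated knockout mice. The ratio of the gap to the range is given for each. In untreated knockout mice, replicate 5 was lowest for Apoa1 (0.795), Apoa4 (0.737) and Apoc3 (0.774), replicate 4 was highest for Mcpt1 (0.956), Mcpt2 (0.835), Ifit3 (0.793) and Ehhadh (0.762), replicate 3 was highest for Alox15 (0.995) and lowest for Retnla (0.84), replicate 2 was highest for Fcer1a (1.00), and replicate 1 was highest for Ccl7 (0.803) and lowest for H2-Q2 (0.738). In TNBS-treated knockout mice, replicate 5 was lowest for H2-Bl (0.666), H2-Q2 (0.738), Gzmb (0.62) and Tnfrsf12a (0.57) and highest for Apoa4 (0.794) and Cgn (0.764), replicate 7 was lowest for Cd40 (0.614) and Icam1 (0.705), replicate 6 was highest for Ccl24 (0.711) and Mmp13 (0.762), and replicate 2 was lowest for Apoc3 (0.988). In untreated wild-type mice, replicate 5 was highest for Chil3 (1.00) and Fcer1a (1.00), both just above the floor, replicate 4 was highest for Sfi1 (0.738), replicate 3 was highest for Sult1c2 (0.715) and lowest for Smad7 (0.727), Saa1 (0.746) and Slpi (0.725), and replicate 2 was lowest for Ccl2 (0.842). In TNBS-treated wild-type mice, replicate 2 was highest for Atrnl1 (0.781) and Apoa1 (0.811) and replicate 3 for Chil3 (0.77).

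Chance is argued against, but not excluded, as the source of the number of called genes in each comparison. Of 100 splits of the arrays into groups of the same sizes, the real one included, 1 gave as many, the real one. Other splits also mix differences between the real groups into the spread, which lowers their counts. The real counts and the highest of the other splits were 2998 and 4 for TNBS in wild type, 1556 and 498 for TNBS in the knockout, 1902 and 1208 for the genotypes with TNBS, 879 and 74 for the genotypes without TNBS, and 363 and 5 for the difference of TNBS effects.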

How the results depend on the processing

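The floor at log2 5, the omission of genes at the floor and the 3 covariates were chosen after seeing the data, and the cause of the changes below was not tested unless stated. Counts of called genes stayed within 1.5 times under the alternatives not named here. Requiring a change of at least 1 left 486 and 262 genes for TNBS in wild type and knockout, 196 and 102 for the genotypes with and without TNBS, and 84 for the difference, as a stricter criterion must. Testing every probe set, which counts more features, gave 4682 for TNBS in wild type and 3345 for the genotypes with TNBS. Fitting the 2 groups alone, with fewer arrays to estimate the spread, gave 856 for TNBS in the knockout and 288 for the genotypes without TNBS. The squamous covariate gave 1231 and 568 for TNBS in wild type and knockout, the Gapdh covariate 813 for TNBS in the knockout and 738 for the genotypes with TNBS, and the muscle covariate 104 for the genotypes without TNBS, where the median of the skeletal muscle list turned to -0.029, as the covariate removes that mean. Leaving out single arrays gave 2250 to 2995, 1014 to 1835, 1391 to 2106, 458 to 923 and 213 to 443 genes for the comparisons in the order above.

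The rise of Tnfrsf12a with TNBS in wild-type mice lost its call with the 2 groups alone (0.70, unchanged in size), a minimum change of 1 (0.70), the replicate block (0.61), and the muscle (0.63) and squamous (0.52) covariates. It was 0.50 without wild-type replicate 2 and 0.83 without wild-type replicate 5, and lost its call without untreated replicates 1, 2 or 4 or TNBS replicates 4 or 6. The lower level in the knockout kept its call under every alternative run. Correlation of TNBS effects across genes gave an r of 0.689 with every probe set, 0.702 with the floor at log2 5, 0.651 with the squamous and 0.687 with the Gapdh covariate. Lists passing with an estimated correlation numbered 2 and 2 for TNBS in wild type and knockout, 1 and 0 for the genotypes with and without TNBS and 0 for the difference; fry passed 8 for the genotypes without TNBS, and 7 passed for the difference without the dimmer probe sets.

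Replicate numbers did not pair the samples: of 31 same-numbered pairs of arrays from different groups, 10 had deviations correlated above 0.1 (range -0.460 to 0.431), and 5 matched their own number best. With the replicate number as a block, a fit that has fewer degrees of freedom, 1230 genes were called for the genotypes with TNBS and 172 for the difference. Of 175 values of named genes, without those of Pnliprp2, H2-M3, H2-Ab1 and H2-K1, no called value changed direction. The calls lost were 20 of 158 with the 2 groups alone, 33 with a minimum change of 1 and 10 with the replicate block. With the floor at log2 5 they were 26, and with the muscle, squamous and Gapdh covariates 18, 19 and 19. A further 4 were lost with the mean of all probe sets, 3 with every probe set and 1 with array weights. Over the fits that left out 1 array 96 were lost. Of 75 values of named lists, the calls lost were 65 with an estimated correlation, 7 with the floor at log2 5, 6, 8 and 3 with the muscle (1 of them the list that turned in sign), squamous and Gapdh covariates, 4 with median centring, 4 without the dimmer probe sets, 3 by fry, 2 with the replicate block (eosinophils, adjusted p = 0.0729, and cytotoxic lymphocytes, 0.0708, for the genotypes with TNBS), 18 over the fits that left out 1 array, and 1 each with array weights, the mean of probe sets and the omission of genes at the floor. A floor at the 20th percentile moved 0 values and tests nothing, and a sex covariate was not run because all arrays fell into 1 class.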

Other observations

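Tests on genes near Tnfrsf12a called in both genotype comparisons were chosen after the results were seen, while those on all called genes and on sex were planned. Further lists fixed before the data were examined passed for TNBS in wild-type mice, not all of them in the knockout. Of 13 endothelial markers 8 rose in wild-type mice (9 adjusted over the list alone; camera adjusted p = 5.9e-07, adjusted p = 0.0953 with an estimated correlation) and 6 in the knockout (6 adjusted over the list alone; adjusted p = 3.1e-06, adjusted p = 0.12 with an estimated correlation). Of 10 dendritic cell markers 6 rose in wild-type mice (6 adjusted over the list alone; adjusted p = 0.00013, adjusted p = 0.0754 with an estimated correlation) and 3 in the knockout (4 adjusted over the list alone; adjusted p = 0.0064, adjusted p = 0.178 with an estimated correlation), and 5 were lower in TNBS-treated knockout than wild-type mice (6 adjusted over the list alone; adjusted p = 9.7e-05, adjusted p = 0.071 with an estimated correlation). Of 8 tuft cell markers 3 rose in wild-type mice (5 adjusted over the list alone; adjusted p = 0.012, adjusted p = 0.223 with an estimated correlation). In the knockout 0 of them passed limma, 1 at an unadjusted p under 0.05 (0 adjusted over the list alone; adjusted p = 0.0718, adjusted p = 0.309 with an estimated correlation, fry adjusted p = 0.0718). In wild-type mice enteroendocrine markers fell in 5 of 11 cases (5 fell and 1 rose adjusted over the list alone; adjusted p = 0.0073, adjusted p = 0.283 with an estimated correlation), and in the knockout 1 of 11 fell (1 adjusted over the list alone) and the list did not pass (adjusted p = 0.142, adjusted p = 0.549 with an estimated correlation). The TNBS effects on the tuft and enteroendocrine lists did not pass a test of their difference between genotypes (adjusted p = 0.255 and 0.116; adjusted p = 0.520 for both with an estimated correlation). In the knockout the tuft list passed under 5 of 24 alternatives, among them without untreated replicate 2 or TNBS-treated replicate 6 (adjusted p = 0.0423 and 0.0384). The enteroendocrine list passed there under 3 of 25, among them without untreated replicates 3 or 4 (0.0240 and 0.0476), and its difference passed without untreated knockout replicates 1 or 2 (0.0411 and 0.0214). In wild-type mice the tuft call was lost with values below log2 5 set to 5 and the enteroendocrine call with centring on medians. In wild-type mice genes of mitochondrial respiration fell in 5 of 17 cases (5 adjusted over the list alone; adjusted p = 0.0011, adjusted p = 0.248 with an estimated correlation), and in the knockout in 3 (5 adjusted over the list alone; adjusted p = 0.008, adjusted p = 0.293 with an estimated correlation), a call that the squamous covariate and the omission of dimmer probe sets ended.

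Apoa1, Apoa4 and Apoc3, apolipoproteins made by the small intestine and liver, varied widely among untreated mice and were near the floor with TNBS. Apoa1 stood at 4.82 ± 3.61 (SD, n = 5) in untreated wild-type and 7.85 ± 2.64 (n = 5) in untreated knockout mice. With TNBS it stood at 2.34 ± 0.26 (n = 6) and 2.22 ± 0.04 (n = 7), and its TNBS effects did not pass a test of their difference (-3.14 ± 1.71, adjusted p = 0.401).

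In both comparisons of knockout with wild type, Kctd5 was lower (-1.13 ± 0.09 with and -1.27 ± 0.10 without TNBS) and Hcfc1r1 higher (0.61 ± 0.06 and 0.65 ± 0.07). Both lie within 20 Mb of Tnfrsf12a on chromosome 17, and both were chosen after their values were seen. Of the genes there called in the same direction in both comparisons, they are the nearest to Tnfrsf12a on either side. For them, linked variants and an effect of the knockout construct on adjacent genes cannot be told apart. Variants of the donor strain carried along with the knockout may account for part of the calls within 20 Mb. Genes called in the same direction in both comparisons were over-represented there outside the H2 genes (9 of 386 against 148 of 17522, odds ratio 2.80, 95% interval 1.25 to 5.52, one-sided Fisher's exact p = 0.0071). For genes outside the H2 genes, an effect of the construct on adjacent genes alone stays open. From 1 to 20 Mb their odds ratio was 2.51 with an interval that includes 1 (0.985 to 5.37, one-sided Fisher's exact p = 0.027). That test does not cover the H2 genes. Over all called genes the odds ratio was 1.96 without TNBS (1.40 to 2.68, one-sided Fisher's exact p = 7.4e-05) and 1.35 with TNBS (1.02 to 1.75, p = 0.017). Over-representation, the sign set beforehand for linked variants, was thus met in both comparisons. With TNBS the upper bound also lay below 2, the sign set against them, so that test cannot decide. Neither odds ratio measures what part of all calls such variants account for. Sex is argued against by sex-linked genes that differed by at most 0.109 with and 0.216 without TNBS.

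H2-Q2 and H2-Bl, class I histocompatibility genes that differ between mouse strains, chosen after their values were seen, were higher in the knockout with TNBS (4.56 ± 0.89 and 2.89 ± 0.62) and without (4.23 ± 1.01 and 3.28 ± 0.70). H2-Q2 stood at 2.47 on untreated knockout replicate 1 and TNBS-treated knockout replicate 5, while wild-type arrays lay at 2.17 to 2.59, and the other knockout arrays at 7.03 to 8.78. Sfi1, on another chromosome, was higher in the knockout by 1.30 ± 0.13 with and 1.45 ± 0.15 without TNBS.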
